A study of Homo sapiens with 6 samples.

How the data were processed

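Gene expression was measured in 2 human cultures, adherent U87MG glioblastoma cells and P4E8, a line of glioma stem-like cells derived from U87MG. Each culture was represented by 3 one-colour Agilent arrays hybridised with Cy3-labelled cRNA made from total RNA. The design text states that the RNA came from separate dishes of each culture, so arrays were treated as replicates of a culture and group was the only term of the model.

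The authors scanned and quantified the arrays with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. The deposited scanner files give an intensity per spot: per the file headers, the processed signal is a background-subtracted and detrended Cy3 intensity, not normalised between arrays, and low values are replaced by a surrogate. Per the file headers, the raw spot mean and the local background median are also intensities, with no correction. Other columns of the deposited files hold the control type and outlier, saturation and detection marks of each spot. The deposited series table holds a ratio for 25587 of the 50599 probes. Its scale was not stated. By comparison it was taken as each processed signal's linear ratio to its array's 75th percentile. That ratio was then taken to be divided by the probe's median over the 6 arrays. Differences between arrays computed that way correlated with the authors' log2 ratio at r of 0.999999 or above on every array. Such a correlation does not depend on an array's scaling factor or a probe's divisor, so it does not establish either. How the authors chose the probes of that table is unknown. Those values were used only as an alternative.

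Control spots and spots marked as outliers were left out. The log2 processed signal minus the array's 75th percentile was averaged over the spots of a probe. A probe counted as detected on an array where at least 0.5 of its spots were well above background by the scanner software's own mark. A gene was tested if its probe was detected on all arrays of at least 1 group, arrays left without a value by an outlier mark aside, with at least 2 arrays of each group holding a value. A gene with several probes was given by the probe with the highest mean signal over the 6 arrays. Probe positions are those of build hg19 per the file headers. Current symbols came from a RefSeq table of assembly GRCh38.p14, used for names only: 30004 probes matched by accession, 3599 by symbol or synonym, and 16996 kept the name in the file. The probes stood for 36268 genes, of which 22601 had a current symbol. In 2401 of these the symbol differs from the file's name. The exon and untranslated-region annotation of hg19 was not used here.

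Differences are P4E8 minus U87MG on the log2 scale, fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with statmod 1.5.0 and version 1.17.8 of the data.table package. P-values were adjusted with the Benjamini-Hochberg method over all genes tested. A 2-fold call needed an adjusted p under 0.05 and a log2 difference of at least 1 in size. Standard errors (SE) are those of the moderated fit, and SD is the spread of the 3 arrays of a group. Where a gene was well above background on all 3 arrays of one group and on none of the other, the fold is a lower bound. It compares the bright group's mean with the dim group's mean of, on each array, the higher of the array's lowest well-above-background signal and the probe's own signal. No fold is given where that bound is under 1.

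The 48 gene lists were tested with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists. They were tested again with a correlation estimated from the arrays and with fry. The lists cover stem cell, astrocyte, neuronal, oligodendrocyte, leukocyte, endothelial, epithelial and fibroblast markers, glioma subtypes, cell cycle, metabolism, stress responses, signalling pathways, matrix and adhesion, immune genes, and gene families. Genes of each chromosome were tested the same way, the Y chromosome left out. Genes were named by a rule: 13 genes fixed by name, the 10 largest differences in each direction among genes well above background on all 6 arrays with a gene symbol, the 6 largest lower bounds in each direction, and in each list up to 4 members with an adjusted p under 0.05 and the largest differences. The main settings, the gene lists, the rule and all alternatives but 1 were chosen before the data were examined. The exception is scaling by the E1A control spots, added after seeing the data.

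Alternatives were quantile normalisation, scaling by the median or by the 75th percentile of genes well above background, normexp background correction with offset 50 followed by quantile normalisation, the authors' table, no filter on dim probes, detection on all 6 arrays, outlier spots kept, every probe tested on its own, the mean over those of a gene's probes with a value on the array, the replicate number as a block, eBayes with trend and robust, array weights, treat at 1.5-fold, and leaving out each array in turn. A scan of windows of 20 neighbouring genes, in steps of 10, was not among the choices made before the data were examined. A window passed if its median difference lay beyond the central 95% range of the lowest and highest windows in 1000 shuffles of the genes and at least 16 of its genes lay on that side. The scan was repeated with 1 gene per family in every 20, and a window that held several genes of a family was not counted.

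The pipeline was tested on simulated data for P4E8 against U87MG with 18252 genes. Of 67 genes changed 1.5-fold, 70.1% were called at an adjusted p under 0.05. Of 67 genes changed 3-fold, 92.5% were called, as were all 66 genes changed 6-fold. No other gene was changed, whereas 11250 of 18818 genes passed in the real data. The Benjamini-Hochberg cutoff depends on the share of changed genes, so these percentages do not give the share called in the real data. No unchanged gene passed the 2-fold call, and 12 unchanged genes passed without it. With nothing moved, 0 of 48 lists and 0 of 23 chromosomes were called. The simulated genes varied independently of each other, so this does not show how often lists of correlated genes are called. With 1 list raised by 0.5 and 1 chromosome raised by 0.3 on the log2 scale, each was called. The number of arrays, 3 per group, limits the precision. The arrays of a group come from dishes of the same culture. SE and p-values therefore describe the spread of dishes and arrays, not that of separately derived lines. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.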

Results

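The series compares adherent U87MG cells, an established human glioblastoma line kept in medium with serum, with P4E8 cells, stem-like cells derived from U87MG and grown as floating spheres in serum-free neurosphere medium with bFGF and EGF. The comparison addresses which genes differ in expression between the adherent line and its stem-like derivative. Medium, growth form and cells differ together between the groups. There were 3 arrays per group, 6 in all, each with 58717 spots for 50599 probes besides controls. The 75th percentile of the processed signal ran from 472 to 569 over the arrays, and 52.6% to 55.0% of spots were well above background. All 6 arrays lay on 1 slide, with U87MG in row 1 and P4E8 in row 2, so slide row and group cannot be told apart. Across 18252 genes, the correlation between arrays was 0.996 to 0.997 within a group and 0.947 to 0.950 between groups. Genes are not independent replicates. The first principal component held 90.9% of the variance.

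SOX2, a transcription factor of neural stem cells, was at least 184-fold higher in P4E8: its log2 signal relative to the array's 75th percentile was -5.89 ± 0.22 in U87MG, below the detection mark on all 3 arrays, and 2.54 ± 0.05 in P4E8 (SD, n = 3 arrays per group; adjusted p = 4.39e-07; probe A_23_P401055, hg19 chromosome 3, 181431877 to 181431936). NES, which encodes the neural progenitor filament protein nestin, was 4.76-fold higher, from 0.49 ± 0.02 to 2.74 ± 0.05 (SD, n = 3; adjusted p = 1.05e-06; probe A_23_P103672, chromosome 1, 156638841 to 156638900). FN1, which encodes fibronectin, differed by -1.72 on the log2 scale (SE 0.09; adjusted p = 3.15e-05), and EGFR, the receptor of EGF, by -1.12 (SE 0.08; adjusted p = 8.06e-05), with all 3 EGFR probes lower. OLIG2, a glial lineage factor, was at least 1.89-fold lower, being well above background on the U87MG arrays alone (adjusted p = 0.000705). CDKN1A, a cyclin-dependent kinase inhibitor, was lower by a log2 difference of -0.51 (adjusted p = 0.00319), as was TUBB3, a neuronal tubulin that lies in a region of chromosome 16 lower in P4E8 (-0.46, adjusted p = 0.000853).

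The other fixed genes differed little, or by an amount that depended on the probe or setting. CD44, a hyaluronan receptor, gave -0.32 (SE 0.06; adjusted p = 0.00337) on its brightest probe and 0.44 on the other. The mean over its probes was 0.06 (adjusted p = 0.479), E1A scaling gave -0.14 (adjusted p = 0.111), and its adjusted p over the alternatives that test for any difference ran from 7.21e-06 to 0.479. MSI1, an RNA-binding protein of neural progenitors, gave -0.49 (SE 0.13; adjusted p = 0.0187). MSI1 missed the threshold, with a difference of -0.40 to -0.49, without U87MG replicate 1 (adjusted p = 0.0567), without U87MG replicate 3 (0.0621), without P4E8 replicate 1 (0.0518), without P4E8 replicate 3 (0.0539) and without the filter on dim probes (0.0586). With E1A scaling MSI1 gave -0.30 (0.0781), over a range from 0.000657. MKI67, a marker of dividing cells, did not pass (0.06, adjusted p = 0.506). With E1A scaling MKI67 gave 0.24 (adjusted p = 0.0354), in a range up to 0.925. PROM1 and GFAP were well above background on no array and were not tested.

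**Figure D1:**
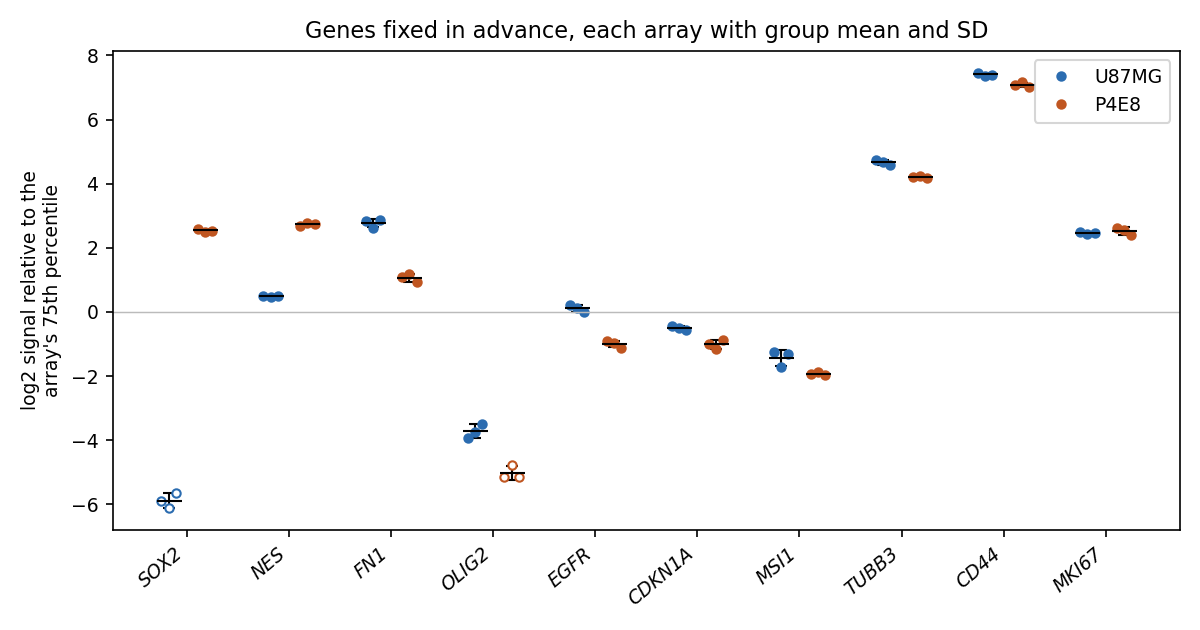
Log2 signal relative to the array's 75th percentile for 10 tested genes fixed by name, 1 point per array, with bars for the group mean and SD (n = 3 arrays per group). Open points are below the detection mark. SOX2 lies at -5.89 in U87MG and at 2.54 in P4E8.

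Of 18818 genes tested, 1042 were at least 2-fold higher and 1284 at least 2-fold lower in P4E8, and 143 and 258 of these passed 8-fold. These counts use fitted differences, also for the 229 genes seen in P4E8 alone and the 493 in U87MG alone. Some of those have a lower bound short of the count they enter. OLIG2 counts as 2-fold lower with a bound of 1.89-fold, and HES4 as 8-fold lower with 4.37-fold. At an adjusted p under 0.05 with no minimum difference, 5318 genes were higher and 5932 lower. Among 18252 genes with values on all arrays, the groups did not overlap in 12393 (67.9%, against 10% by chance), and each of the 212 named genes past the threshold had its groups apart on all arrays. Most named genes were chosen for large differences in these same data, so their separation is no independent support. Of the 213 named genes, 39 lost their call in a test against a minimum of 1.5-fold, CD44, MSI1, TUBB3 and CDKN1A among them. Of 432 genes with a 2-fold call and more than 1 tested probe, 6 had a probe called the opposite way. The 2-fold counts fell to 512 and 684 with normexp correction and quantile normalisation, and to 687 and 752 where detection on all 6 arrays was required. Scaling by the E1A control spots, added after seeing the data, moved the median of all genes by 0.19 on the log2 scale, and the share of 2-fold calls that were higher was then 57.4% against 44.8%. All differences are relative to the 75th percentile.

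**Figure D2:**
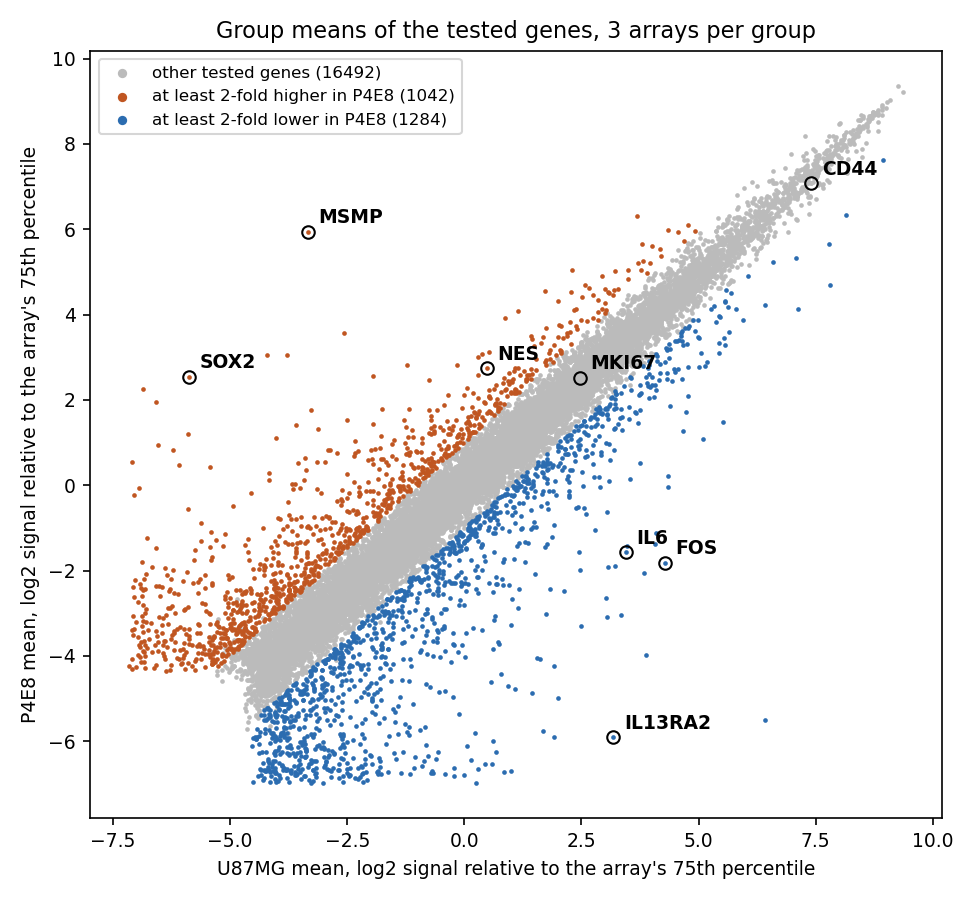
Mean log2 signal relative to the array's 75th percentile in U87MG (horizontal axis) and P4E8 (vertical axis), 1 point per tested gene, n = 3 arrays per group. Orange marks the 1042 genes at least 2-fold higher in P4E8 and blue the 1284 at least 2-fold lower. SOX2, NES and MSMP lie above the diagonal and IL13RA2, FOS and IL6 below it.

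The largest rise among genes detected on all 6 arrays was in MSMP, a secreted microseminoprotein, at 622-fold (log2 difference 9.28, SE 0.14, n = 3 per group; adjusted p = 5.92e-07; chromosome 9, 35752991 to 35753050). CNTNAP3B, a contactin-associated protein gene in a chromosome 9 region that was higher as a whole, was 154-fold higher (7.27, SE 0.21), with 4.82 on its other probe. CYB5R2, a cytochrome b5 reductase, was 70.5-fold higher (6.14, SE 0.07). The integrin subunit ITGB8 rose by 4.50, the receptor ROR1 by 4.28 (1.79 on its lowest probe), the guanine nucleotide exchange factor DOCK4 by 4.44 and FABP7, the brain fatty acid-binding protein of radial glia, by 4.08. SECTM1 (5.02), the granin SCG2 (5.01) and the atypical protein kinase C PRKCZ (5.13) completed the set, although the other PRKCZ probe gave -0.08. Among genes detected in P4E8 alone, SOX2 was followed by the sodium-calcium exchanger SLC24A3 (at least 151-fold), the potassium channel-interacting protein KCNIP3 (at least 60.7-fold), FGD4 (at least 46.1-fold, with a difference of 2.99 on its lowest probe), the BMP antagonist NOG (at least 44.2-fold) and the forkhead factor FOXS1 (at least 39.0-fold).

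CD70, a ligand of the tumour necrosis factor family, was 84.2-fold lower in P4E8 (log2 difference -6.40, SE 0.18, n = 3 per group; adjusted p = 2.92e-06; chromosome 19, 6585867 to 6585926). FOS, an immediate early transcription factor, was 68.2-fold lower (-6.09, SE 0.09), the glycoprotein gene GPNMB 58.7-fold (-5.87, SE 0.05), FAP, the fibroblast activation protein, 50.8-fold (-5.67, SE 0.09) and the cytokine IL6 32.5-fold (-5.02, SE 0.08, with -3.32 on its other probe). The lipase-related PNLIPRP3 (-6.12), the proteoglycan serglycin gene SRGN (-5.79), the chemokine CCL3 (-5.21) and ZDHHC4 (-5.11) were also among the 10, as was the interleukin-1 receptor antagonist IL1RN (-5.68, with -0.85 on its other probe). Among genes detected in U87MG alone, the interleukin-13 receptor IL13RA2 was at least 226-fold lower in P4E8 (chromosome X, 114238591 to 114238650). LAYN followed (at least 98.4-fold), then TMEM273 (at least 80.1-fold, -3.40 on its weakest probe), the chemokine receptor CCR1 (at least 67.2-fold), the keratin-associated KRTAP1-5 (at least 49.5-fold, -3.13 on its other probe) and APBB1IP (at least 39.5-fold, -5.10 on its other probe).

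Of the 48 gene lists, camera called 16, of which 4 were higher and 12 lower in P4E8. None of the 16 held with an estimated correlation, where the smallest adjusted p was 0.230. For each called list but the ribosomal proteins the adjusted p with an estimated correlation was the highest of any setting. In the lysosome and proneural lists the estimate was -0.031 and -0.034, below the preset of 0.01. Their camera adjusted p still rose from 0.00183 and 0.00278 to 0.230, so a higher correlation among their genes does not account for it. In every other called list the estimate lay above the preset. With an estimated correlation camera takes its degrees of freedom from the 6 arrays, and with the preset from the genes. A call lost there therefore does not show that correlation removed it, or that the list did not shift. How much each of these removed was not tested. Normexp and quantile brought the medians of the YAP and SRF, TGF-beta and NF-kappaB lists to -0.53, -0.60 and -1.32, and E1A scaling those of the mesenchymal, integrin and lysosome lists to -0.26, -0.33 and -0.33, with all 6 still called. By fry, which tests whether a list's genes move one way on balance, 43 of 48 lists passed, and all 48 passed its test for change in either direction. Fry does not set a list against the other genes. Of 18818 genes tested, 11250 had an adjusted p under 0.05 in the limma fit, so passing fry does not set a list apart from genes at large. Counts of members below are at an adjusted p under 0.05 over all genes tested. Members that were not tested are left out of them. Among others, that left 8 of 17 astrocyte, 7 of 14 oligodendrocyte, 7 of 15 leukocyte and 7 of 15 epithelial markers. Counts adjusted over the list alone were the same except in 8 lists, where both are given.

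Sterol and fatty acid synthesis genes were higher in P4E8. Of 24 measured cholesterol biosynthesis genes, 23 rose and 0 fell, with a median log2 difference of 1.19 (camera adjusted p = 4.36e-12; adjusted p = 0.230 with an estimated correlation). HMGCS1, the hydroxymethylglutaryl-CoA synthase, rose by 2.47 (SE 0.06, n = 3 per group), ACAT2 by 2.27 (SE 0.07) and the squalene synthase FDFT1 by 1.97 (SE 0.07). Of 12 fatty acid synthesis genes, 10 rose and 0 fell, with a median of 0.82 (adjusted p = 0.000157; adjusted p = 0.237 with an estimated correlation). The lipin LPIN1 rose by 1.97 (0.28 on its lowest probe), the desaturase FADS2 by 1.80 and the acyl-CoA synthetase ACSL3 by 1.14. SREBF1, a transcription factor of lipid synthesis, gave 0.96 on its brightest probe and -0.30 on the other, and the mean over its probes gave 1.34 but missed the threshold (adjusted p = 0.221, the highest of a range from 2.52e-10). That mean lies beyond both probes because the dimmer one has no value on 1 P4E8 array, where the brighter one stood alone. Sterol efflux genes, which respond to the sterol receptor LXR, went both ways: of 8 measured, 3 were higher and 3 lower, with a median of -0.06 that was 0.13 with E1A scaling (camera adjusted p = 0.558). ABCA1, a cholesterol exporter, gave -1.96, the lipid carrier APOE -2.33 and the phospholipid transfer protein PLTP -1.95, while SMPDL3A rose by 1.32.

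Immediate early genes, which growth factors and stress induce within minutes, were lower in P4E8: 14 of 16 fell and 0 rose, with a median of -1.58 (camera adjusted p = 2.47e-06; adjusted p = 0.230 with an estimated correlation). FOSB gave -6.15, being well above background on 2 of 3 P4E8 arrays, and EGR1 differed by -4.00 (SE 0.08, n = 3 per group) and EGR2 by -2.99 (SE 0.10). Of 24 NF-kappaB cytokines and chemokines, 20 fell and 3 rose, with a median of -2.31, or -1.95 with bounds for genes seen in 1 group (adjusted p = 8.29e-07; adjusted p = 0.237 with an estimated correlation). BIRC3, an inhibitor of apoptosis, was at least 13.6-fold lower. The neutrophil chemokine CXCL2 differed by -4.40 (SE 0.10), the growth factor CSF3 by -4.05 (SE 0.05) and IL6 by -5.02. Of the immediate early list 2 members, and of the NF-kappaB list 4, stand in other lists.

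Targets of YAP and SRF, regulators tied to cell spreading and actin, were lower: 23 of 25 fell and 2 rose, with a median of -0.89 (camera adjusted p = 7.24e-07; adjusted p = 0.230 with an estimated correlation). The matricellular CCN1 gave -3.40 (SE 0.07, n = 3 per group), the myosin light chain MYL9 -2.94 (SE 0.05), the calponin CNN1 -2.84 (SE 0.15) and the tissue factor F3 -2.73 (SE 0.11). Of 19 TGF-beta and BMP targets, 14 fell and 4 rose, with a median of -0.95 (adjusted p = 0.00827; adjusted p = 0.457 with an estimated correlation). SMAD6, an inhibitor of BMP signalling, gave -3.78 and TGFBI, a matrix protein induced by TGF-beta, -3.11, whereas the pseudoreceptor BAMBI rose by 3.21 and NOG was at least 44.2-fold higher. Of 26 integrin and focal adhesion genes, 18 fell and 4 rose, or 18 and 5 adjusted over the list alone, with a median of -0.52 (adjusted p = 0.0119; adjusted p = 0.334 with an estimated correlation). The integrin subunits ITGB8 (4.50) and ITGA6 (3.64, SE 0.09) rose, and ITGA11 (-1.69) and the tensin TNS1 (-1.63, with -6.85 on its other probe) fell. Of the YAP and SRF list 4 members, and of the TGF-beta list 5, stand in other lists.

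Matrix genes moved both ways. Of 30 collagens and matrix proteins, 18 were lower and 9 higher, with a median of -0.61, and camera did not call the list (adjusted p = 0.0733). Camera called the collagens with no filter on dim probes (adjusted p = 0.00515), with the mean over probes (0.0427) and with E1A scaling (0.00310), in a range over all settings from 0.000184 with fry to 0.688. The microfibril gene FBN1 fell by 2.80 (SE 0.11, n = 3 per group) and the basement membrane collagen COL4A6 rose by 2.82 (SE 0.10). Of 26 matrix proteases and inhibitors, 16 were lower and 6 higher, with a median of -0.50 (adjusted p = 0.0591). The protease list passed in 11 of the other settings, among them leaving out U87MG replicate 1 (adjusted p = 0.0351) or U87MG replicate 3 (adjusted p = 0.0476), in a range over all settings from 6.74e-05 to 0.472. Its member MMP3, a stromelysin, gave -7.86, with values on 2 U87MG arrays, both well above background, and on 3 P4E8 arrays, 2 of which were. The proteases ADAMTS5 (-3.53) and ADAMTS1 (-2.93) were lower, and ADAM19 rose by 2.73. Of 12 fibroblast markers, 8 fell and 1 rose, or 8 and 2 adjusted over the list alone, with a median of -0.92 (adjusted p = 0.0226; adjusted p = 0.515 with an estimated correlation). The proteoglycans DCN and LUM were at least 33.9-fold and 10.9-fold lower, with -3.73 on the other DCN probe, THY1 was at least 8.79-fold lower, and FAP fell by 5.67. The fibroblast list was not called where detection on all 6 arrays was required (median -0.13, adjusted p = 0.252), and 6 of its 12 members stand in other lists.

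Hypoxia response genes were lower in P4E8: 19 of 23 fell and 1 rose, with a median of -0.91, or -0.76 with bounds (camera adjusted p = 3.86e-05; adjusted p = 0.472 with an estimated correlation). The carbonic anhydrase CA9 gave -3.40 (SE 0.19, n = 3 per group), NDRG1 -2.33 (SE 0.23) and the peptide hormone ADM -2.11 (SE 0.08), while the chemokine receptor CXCR4 was at least 2.28-fold higher. Of 21 glycolysis genes, 17 fell and 2 rose, with a median of -0.60 (adjusted p = 0.00175; adjusted p = 0.472 with an estimated correlation). The hexokinase HK2 gave -1.92, the glucose transporter SLC2A1 -1.33, the enolase ENO2 -1.29 and the aldolase ALDOC -1.28. Of 21 lysosome and autophagy genes, 15 fell and 3 rose, with a median of -0.51 (adjusted p = 0.00183; adjusted p = 0.230 with an estimated correlation). The cathepsins CTSB (-1.55) and CTSD (-1.54) fell, CTSZ was at least 2.03-fold lower, and the autophagy receptor SQSTM1 fell by 1.15. Of 11 metallothioneins, metal-binding proteins, 10 fell and 0 rose, with a median of -0.61, or -0.58 with bounds (adjusted p = 0.000656; adjusted p = 0.339 with an estimated correlation). MT1G was at least 20.7-fold lower, MT1F gave -1.84 and MT1M -0.74.

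Lists of glioma subtypes were called in opposite directions. Only 10 of the 18 proneural genes were measured. Of these 10, 8 rose and 1 fell, with a median of 1.10, or 1.00 with bounds (camera adjusted p = 0.00278, and 0.230 with an estimated correlation). The proneural list kept its call with a median of 0.29 with no filter on dim probes, 0.50 with normexp and 0.50 where detection on all 6 arrays was required. Besides SOX2 these included KLRC3 (2.38, SE 0.11, n = 3 per group), the growth factor receptor PDGFRA (2.21, SE 0.07) and ERBB3 (1.75, SE 0.20), and the member that fell was OLIG2. Of 27 mesenchymal genes, 18 fell and 4 rose, or 18 and 6 adjusted over the list alone, with a median of -0.45 (adjusted p = 0.000939; adjusted p = 0.339 with an estimated correlation). TGFBI gave -3.11 (SE 0.06), the smooth muscle actin ACTA2 -2.64 (SE 0.04) and the transcription factor SNAI2 -1.93 (SE 0.05). Of the proneural list 5 members, and of the mesenchymal list 11, stand in other lists.

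Neural and glioma stem cell markers went both ways: of 22 measured, 10 were higher and 9 lower, with a median of 0.06 that was -0.01 under median scaling (camera adjusted p = 0.653). SOX2, NES, FABP7 and ITGA6 were higher, and the transcription factor SALL2 was at least 4.16-fold lower. In this list 10 members stand in other lists. Of 8 astrocyte markers, 3 were higher and 5 lower (median -0.47, adjusted p = 0.495): APOE fell by 2.33 and SOX9 rose by 1.44 (SE 0.05, n = 3 per group). Of 10 neuronal markers, 3 were higher and 5 lower (median -0.23, adjusted p = 0.512): the synaptic SNAP25 fell by 2.03 and the growth cone protein GAP43 rose by 1.15. Of 7 oligodendrocyte lineage markers, 2 were higher and 2 lower (adjusted p = 0.531), and the median was 0.02, or -0.05 under median scaling. PDGFRA was the largest difference among them and the glycolipid enzyme UGT8 rose by 0.84.

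Replication-dependent histone genes, whose transcripts lack a poly(A) tail, were higher in P4E8: 20 of 21 rose and 1 fell, with a median of 0.73 (camera adjusted p = 9.21e-10; adjusted p = 0.272 with an estimated correlation). H2AC20 rose by 1.37 (SE 0.06, n = 3 per group), and H1-2 and H1-3, which lie in a chromosome 6 region that passed the scan of neighbouring genes, by 1.33 (SE 0.05) and 1.29 (SE 0.05). H1-5 in the same region fell by 2.01, with values on 2 of 3 U87MG arrays. G1/S and DNA replication genes were not called: 10 of 30 were higher and 7 lower, with a median of 0.10 (adjusted p = 0.325). CCNE1, a cyclin of S phase entry, fell by 0.86, and the replication factors CDT1 (-0.73) and GINS2 (-0.65), both in the lower region of chromosome 16, fell, while the primase PRIM1 rose by 0.59. Of 29 G2/M and mitosis genes, 9 were higher and 3 lower, or 6 and 2 adjusted over the list alone, and the median was 0.04, or -0.03 under median scaling (adjusted p = 0.396). The centromere chaperone HJURP rose by 0.63 and the kinase NEK2, in a higher region of chromosome 1, by 0.52. Of 40 ribosomal protein genes, 20 fell and 2 rose, or 19 and 0 adjusted over the list alone, with a median of -0.13 that was 0.06 with E1A scaling (adjusted p = 0.0226; adjusted p = 0.472 with an estimated correlation). RPL13, in the lower region of chromosome 16, gave -0.82 and RPS3 -0.44. That call was lost under 5 settings.

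Camera called none of the 3 lists of markers of further cell types. Fry passed each, as it did most lists (leukocyte adjusted p = 0.00507, endothelial 0.0155, epithelial 0.000128). The highest adjusted p of any setting were 0.722, 0.952 and 0.472. Of 7 leukocyte and microglia markers, 1 was higher and 4 lower (median -0.30, camera adjusted p = 0.304), among them the receptor CSF1R (-0.66, SE 0.04, n = 3 per group) and CD68 (-0.58). Of 8 endothelial and pericyte markers, 2 were higher and 2 lower (median 0.38, adjusted p = 0.565): the receptor TEK fell by 2.23 and the potassium channel KCNJ8 rose by 1.49. Of 7 epithelial markers, 4 were higher and 2 lower (median 0.79, adjusted p = 0.153): the keratins KRT18 and KRT19 rose by 2.24 and 0.87, and KRT8 by 1.02 on its brightest probe, with -0.06 on the other.

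**Figure D3:**
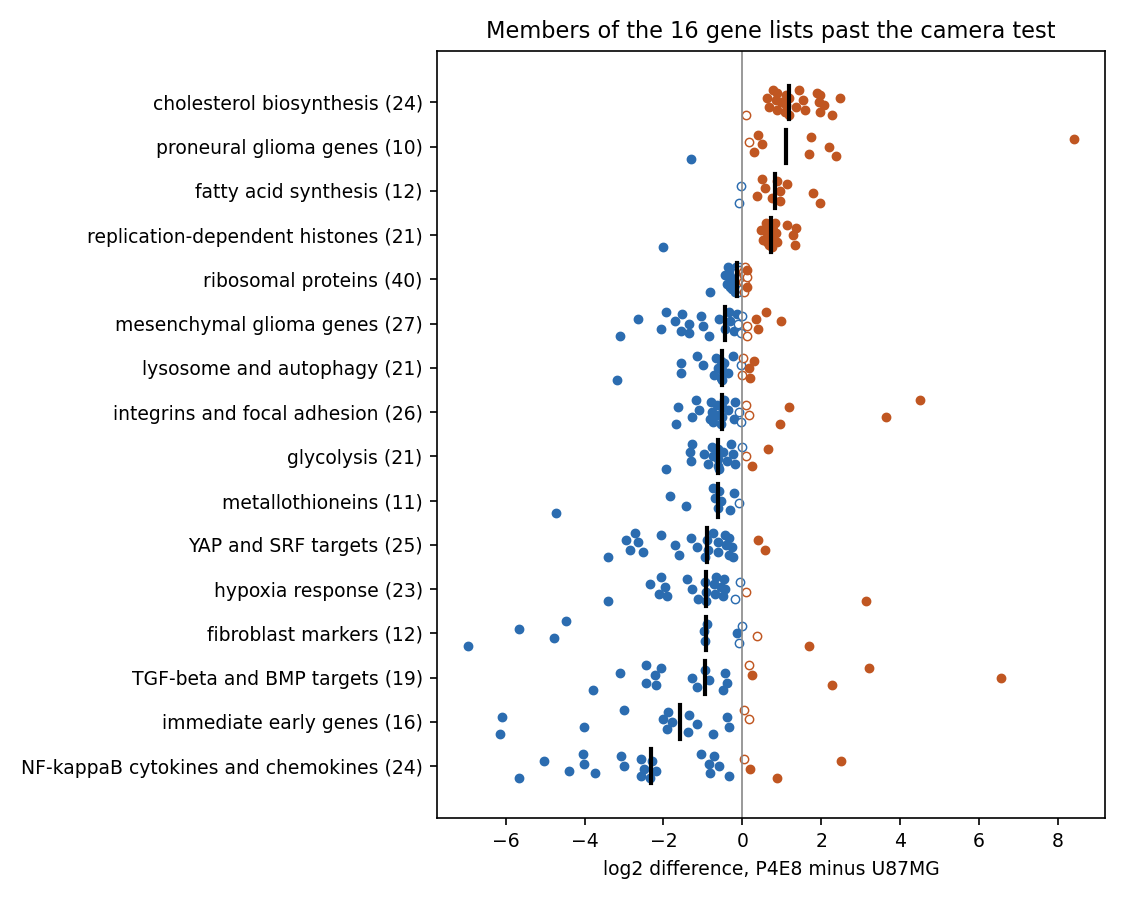
Log2 difference (P4E8 minus U87MG) of each measured member of the 16 lists called by camera, 1 point per gene, with a bar at the list's median and the number of members measured in brackets. Filled points have an adjusted p under 0.05, orange is higher and blue lower in P4E8, and genes seen in 1 group are drawn at their fitted value. Medians run from -2.31 (NF-kappaB cytokines and chemokines) to 1.19 (cholesterol biosynthesis), and that of the ribosomal proteins is above 0 with E1A scaling.

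No chromosome was called as a whole. Camera called 0 of 23 chromosomes (smallest adjusted p = 0.843), 0 at an unadjusted p under 0.05 and 0 with an estimated correlation, and chromosome medians ran from -0.11 to 0.05. In the scan of 20 neighbouring genes, 19 of 1833 windows passed, in 7 regions (hg19). At 16:85706645 to 90036576, 51 of 70 tested genes were lower and 2 higher, with a median of -0.67 against 0.08 on the rest of the chromosome. COX4I1, a subunit of cytochrome c oxidase, gave -0.86 there (SE 0.05, n = 3 per group) and the amino acid transporter SLC7A5 was 8.02-fold lower (SE 0.16 on the log2 scale). At 16:68334588 to 75205774, 53 of 70 genes were higher and 8 lower (median 0.48). On chromosome 9, from 38542517 to 45362806, 29 of 40 genes were higher and 1 lower (median 1.37). At the histone genes of chromosome 6, from 25726563 to 28063400, 63 of 80 were higher and 5 lower (median 0.62). The other regions were 1:209406403 to 211923228 (median 0.59), 5:140216279 to 140742054 at the protocadherin genes (median 0.75) and 16:2036685 to 2312343 (median 0.59), each with 20 genes tested, of which 16, 17 and 16 were higher.

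**Figure D4:**
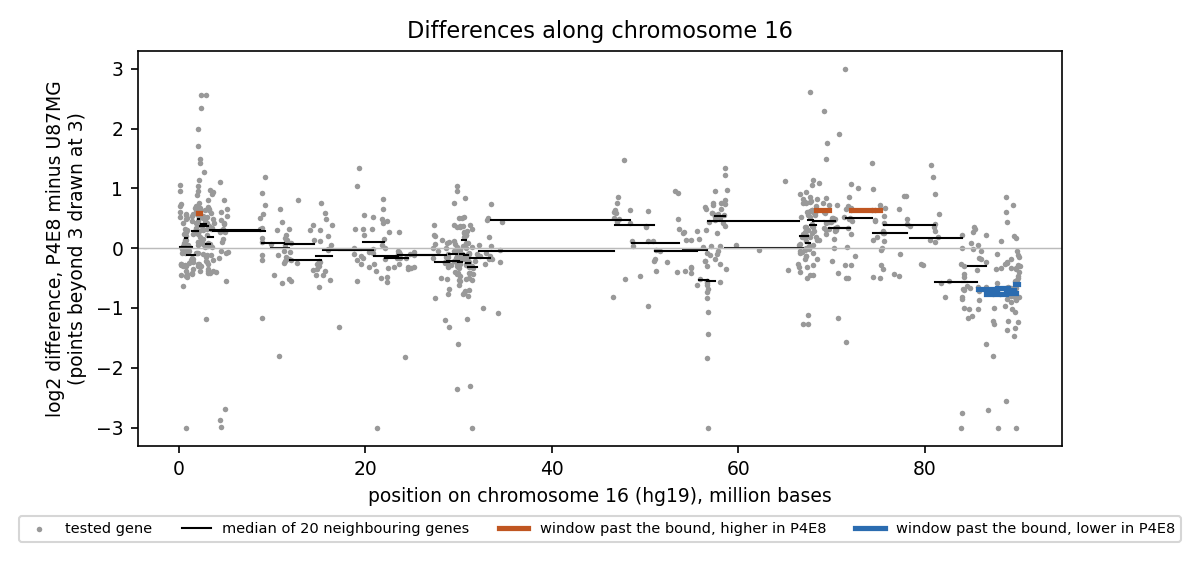
Log2 difference (P4E8 minus U87MG) of each tested gene along chromosome 16 (hg19 position in Mb), with points beyond 3 drawn at 3 and horizontal lines for the median of each window of 20 neighbouring genes. Windows that passed are orange where higher and blue where lower in P4E8. The region from 85706645 to 90036576 has a median of -0.67.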

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

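The tests of S phase genes, of the chromosome 6 segment, of near-identical gene copies and of sterol efflux genes were chosen only after the result was seen. The chromosome 6 test first used the 60 genes given below, whose interval lay under the bound, and was changed to the 17 genes after these values were seen, which left the explanation open. The test of near-identical copies was also changed after its values were seen, to count no window with several genes of a family, which left it open for chromosome 6. The tests of RNA length, of RNA without a poly(A) tail and of neighbouring genes were set out before their results were seen.

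Of 96 ERCC control probes, which match synthetic RNAs that the labels do not mention, 3 were well above background and above the negative controls on all 6 arrays, in data outside the comparison. Their median processed signals over the arrays were 34.4 (ERCC-00092_138), 118 (ERCC-00148_99) and 28.5 (ERCC-00170_100), against 24.5 for the highest 99th percentile of the 308 negative-control spots of an array.

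Replication-dependent histone transcripts were higher in P4E8, with a median log2 difference of 0.73. Shorter RNA in one group is argued against: over 2274 genes with probes at least 500 bases apart, the upstream minus the downstream probe's difference had a median of -0.00443 (95% interval -0.0158 to 0.00701). A different copy number of the chromosome 6 segment stays open: the 17 other genes between the first and last of these histone genes there had a median of 0.32 (95% interval 0.04 to 0.42, across the bound of 0.36), although 23 in the scanned region had 0.25 (-0.07 to 0.33), 60 from 24418746 to 29798753 had 0.14 (0.03 to 0.32) and 2 histone genes elsewhere 1.05. Different priming of RNA without a poly(A) tail stays open, since 246 other such transcripts had a median of 0.19 (95% interval 0.10 to 0.25), above 0 and short of the histones. More cells in S phase may also contribute and stays open, since the 30 G1/S and DNA replication genes had a median of 0.10 (SD 0.35 over members) and were not called by camera, and the difference between the cultures themselves was not tested apart from these.

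Genes that differ lay beside each other on chromosomes 1, 5, 6, 9 and 16: 19 of 1833 windows of 20 genes passed the bounds of -0.58 and 0.57. Probes that read near-identical neighbouring copies are argued against in 3 regions, on chromosome 1 and the higher and lower regions of chromosome 16 that hold 70 genes each, where 10 windows passed again with 1 gene per family (of 1277, bounds -0.56 and 0.54). In the 4 other regions that explanation stays open: with 1 gene per family 2 of them had a median beyond the bound, 1.43 over 9 genes on chromosome 9 and 0.55 over 17 genes on chromosome 16, the chromosome 6 region had 0.31 over 14 genes, and the protocadherin region kept 4 genes, too few to test. A different copy number of these segments stays open: the 19 windows are the pattern itself and add nothing for or against it, and no DNA was measured here. Regulation of neighbouring genes that differs between the cultures was not tested.

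Cholesterol biosynthesis genes were higher in P4E8, with 23 of 24 higher and a median of 1.19. A candidate explanation is that less sterol reaches cells in serum-free medium, which would lower the genes of sterol efflux. Those 8 genes had a median of -0.0606 (SD 1.33 over members; camera adjusted p = 0.558) with members on both sides, so the test decides nothing. Medium and cells differ together, so medium and the derivation of the line cannot be told apart.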

How the results depend on the processing

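Scaling by the E1A control spots was the alternative added after seeing the data. Of 1008 values of the gene lists under the alternatives, 940 kept their direction and side of the threshold, 22 lost a call, 45 gained one and 1 reversed. Camera with an estimated correlation gave 16 of the 22 losses, and fry gave 26 of the 45 gains and the reversal. Both change the test and not the processing. Of 4407 values of the named genes, 4333 were kept, 72 lost a call, 1 gained one and 1 reversed, and 172 of 213 genes kept theirs in every setting where they had a value. Treat at 1.5-fold, which also changes the test, gave 39 of the 72 losses. Of 89 counts and summaries, 79 stayed within 1.5 times or 1 SD of the main value. With normexp and quantile, 512 genes were at least 2-fold higher and 684 lower, and the similarity of arrays (mean correlation within groups minus that between groups, 0.0477 in the main setting) was 0.0278, and the cause was not tested. Detection on all 6 arrays tests fewer genes by construction and gave 687, 752 and 0.0288. The similarity was 1.74 in the authors' values, which are centred per probe by construction, and 0.0170 with no filter, which adds dim probes. CD44 reversed to 0.0563 with the mean over its probes, which point in opposite directions (adjusted p = 0.479, the highest of a range from 7.21e-06, treat at 1.5-fold aside). The cell-cell adhesion list reversed with fry, which tests another hypothesis (median 0.27, adjusted p = 0.000466, in a range up to 0.936). Leaving out each array in turn gave 1011 to 1090 genes 2-fold higher, 1258 to 1306 lower, 9667 to 10517 at an adjusted p under 0.05, a similarity of 0.0460 to 0.0490 and 0 chromosomes. Of the 16 called lists, 14 kept the call in all 19 settings with camera's preset correlation. The ribosomal proteins kept it in 14, losing it under quantile normalisation (adjusted p = 0.658), the 75th percentile of genes well above background (0.0513), normexp (0.659), the mean over probes (0.0752) and E1A scaling (0.744). The fibroblast list kept it in 18. The lists have no value with every probe on its own or with treat, and of the 213 named genes 169 have one where detection on all 6 arrays is required and 207 to 212 where an array is left out. Signal over background limits what can be said of 229 genes seen in P4E8 alone and 493 in U87MG alone, for which no fold but a lower bound can be had.

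The replicate numbers do not pair the samples: the correlation of residuals between arrays of the same number was 0.0557, -0.0323 and -0.0142, and 2 of 6 arrays correlated best with their own number. With the replicate number as a block, 1037 genes were at least 2-fold higher, 1278 lower and 10295 at an adjusted p under 0.05. That block shared 2305 of the 2326 main 2-fold calls, and the calls of the 213 named genes and 48 lists were the same.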

Other observations

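Of 26 interferon-stimulated genes, 14 were higher and 7 lower, with a median of 0.37 (camera adjusted p = 0.0733; adjusted p = 0.0364 under median scaling, in a range from 0.000370 to 0.515). The antiviral RSAD2 was at least 3.21-fold and the synthetase OAS1 at least 3.15-fold higher, OAS2 rose by 1.71 (SE 0.06, n = 3 per group) and BST2 fell by 2.21 (SE 0.09). Of 20 antigen presentation genes, 5 were higher and 3 lower, or 5 and 2 adjusted over the list alone (median 0.04, adjusted p = 0.325): the proteasome subunit PSMB9 rose by 0.78 and the peptide transporter TAP1 by 0.54. Of 13 complement and acute phase genes, 2 were higher and 6 lower (median -0.14, adjusted p = 0.508): C3 gave -5.45 on 2 P4E8 arrays and CFB fell by 1.91. Of 26 growth factor receptors and ligands, 7 were higher and 14 lower, or 8 and 15 adjusted over the list alone (median -0.44, adjusted p = 0.214): the receptor NTRK3 fell by 3.48, with -0.13 on its other probe, and the ligand EREG gave -2.52. Of 22 Wnt and Hedgehog pathway genes, 4 were higher and 10 lower (median -0.12, adjusted p = 0.254): the Wnt inhibitor DKK1 (-3.16) and WNT5B (-2.94) fell and RNF43, which removes Wnt receptors, rose by 2.78. Of 10 Notch pathway genes, 4 were higher and 6 lower (median -0.45, adjusted p = 0.508), with HES4 at least 4.37-fold lower and the receptor NOTCH3 at -1.70. Of 21 ERK pathway feedback targets, 8 were higher and 11 lower (median -0.23, adjusted p = 0.512), with the ephrin receptors EPHA2 at 1.01 and EPHA4 at -1.01. Of 15 retinoid pathway genes, 8 were higher and 4 lower (median 0.75, adjusted p = 0.285): DHRS3, a retinaldehyde reductase, rose by 2.83 and the retinol transporter STRA6 was at least 4.16-fold lower. Of 17 cell-cell adhesion genes, 9 were higher and 8 lower (median 0.27, adjusted p = 0.656), with the cadherin CDH13 at -3.24, or -2.20 on its other probe.

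Of stress and metabolic lists, 22 ATF4 targets gave 6 higher and 13 lower (median -0.25, camera adjusted p = 0.0733, in a range over all settings from 6.74e-05 with fry to 0.478), with SLC7A5, in the lower region of chromosome 16, 8.02-fold lower and CEBPB at -1.56. Camera called the ATF4 targets with no filter on dim probes (adjusted p = 0.00143) and with E1A scaling (adjusted p = 0.0389, median -0.06). Of 21 NRF2 and oxidative stress genes, 8 were higher and 11 lower (median -0.20, adjusted p = 0.480), with the superoxide dismutase SOD2 at -2.29 (SE 0.04, n = 3 per group) and the heme oxygenase HMOX1 at -2.24 (SE 0.06). Of 18 unfolded protein response genes, 7 were higher and 5 lower (median 0.11, adjusted p = 0.503), with XBP1 at -0.59 and HSP90B1 at 0.49. Of 34 oxidative phosphorylation genes, 10 were higher and 7 lower (median 0.05, adjusted p = 0.437), with SDHC at -0.99 and COX4I1, in the lower region of chromosome 16, at -0.86. Of 17 drug efflux and detoxification genes, 4 were higher and 10 lower (median -0.28, adjusted p = 0.254), with the exporter ABCC2 at -3.87. Of 17 ganglioside and glycan synthesis genes, 7 were higher and 5 lower (median 0.09, adjusted p = 0.688): FUT9 was at least 3.44-fold higher and the sialyltransferase ST3GAL5 rose by 3.09. Of 19 ion channels and glutamate receptors, 8 were higher and 8 lower (median 0.08, adjusted p = 0.629), with KCNA2 at least 1.96-fold higher and the purine receptor P2RX7 at -1.93. Of 22 apoptosis regulators, 7 were higher and 6 lower (median -0.00, adjusted p = 0.639), with HRK at least 4.97-fold lower. Of 18 CDK inhibitors and p53 targets, 4 were higher and 6 lower (median -0.01, adjusted p = 0.718), with BTG2 at 1.18 and GADD45B at -0.93. Of 19 HOX genes, 10 were higher and 7 lower (median 0.26, adjusted p = 0.437), with HOXD10 at least 4.23-fold lower and HOXA3 at 1.77. The HOX list was called where detection on all 6 arrays was required (median 0.38, adjusted p = 0.0365, in a range from 0.0122 with fry to 0.810). Of 13 cancer-testis antigens, 3 were higher and 8 lower, or 4 and 8 adjusted over the list alone (median -0.98, or -0.59 with bounds; adjusted p = 0.149), with SSX1 at least 3.87-fold lower and MAGEC2 at 2.83. Camera called these antigens with no filter on dim probes (median -0.49, adjusted p = 0.0176) and with E1A scaling (median -0.80, adjusted p = 0.0114), in a range from 6.74e-05 with fry to 0.981.

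Median, mean and camera differed in sign in 3 lists. The HOX genes had a median of 0.26 and a mean of -0.24 with camera pointing up, and the apoptosis regulators a median of -0.00 and a mean of -0.27 with camera pointing up and fry down. The cell-cell adhesion genes had a median of 0.27 and a mean of -0.14 with camera pointing up and fry down. Fry also pointed down in the ganglioside and glycan synthesis genes, where the median was 0.09, the mean 0.30 and camera pointed up. Under E1A scaling the medians of the Wnt and Hedgehog, complement, CDK inhibitor and apoptosis lists were above 0. Median scaling put those of antigen presentation and oxidative phosphorylation below 0. Members that stand in other lists number 5 of the growth factor receptors, 5 of the apoptosis regulators, 4 of cell-cell adhesion, 3 each of drug efflux and CDK inhibitors, and 2 each of the ATF4, ERK, retinoid and NRF2 lists.

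The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 2326 2-fold calls against 0 in the highest of the others, 11250 genes at an adjusted p under 0.05 against 0, and 16 lists by camera against 13. It was the 1 split with as many in each case. Every other split puts arrays of both cultures in each group, so the difference between the cultures enters its spread. Those splits therefore do not show what arrays without a difference would give. With an estimated correlation every split gave 0 lists, and by fry the real split gave 43 and the others 0.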
